A study of Arabidopsis thaliana with 42 samples.

How the data were processed

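RNA of whole 7-day-old seedlings of wild type (Columbia), GR-REV and KAN1-GR was measured on 42 Affymetrix ATH1 arrays with 22810 probe sets. Per the labels, seedlings were given 50 µM DEX for 0, 30, 60 or 120 min, each sample came from a flask of its own, and wild-type replicates 1 to 3 were grown with GR-REV (day 1) and 4 to 6 with KAN1-GR (day 2). KAN1-GR and the day 2 wild type have no 120 min samples. Arrays were grouped by line, time and day into 14 groups of 3, and their number limits the precision. Replicate numbers were not taken to pair samples.

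The deposited values are log2 values made by the authors with GCRMA (version not given in the sources used here). The log base is not stated in the labels and was taken from the method. Each probe set had been centred on the median of the 6 wild-type arrays at 0 min, which was checked on the values, so absolute levels are not kept. The step that did this is not named in the sources used here. A second deposited table held identical values (largest difference 0) and p-values of the authors' two-way ANOVA for 16164 probe sets, a unit other than expression, with no p-value for 6646. The tool and the criterion behind the blanks are not given in the sources used here. No array pair was identical. Within groups, Pearson's r of centred values was 0.161 to 0.904.

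Gene lists, comparisons, tests and the rule for named genes were chosen before the data were examined. Several planned steps need absolute levels and were changed after the values were seen. A filter on log2 level (4, with 6 as an alternative) was replaced by testing the probe sets that have an ANOVA p-value, less 35 control probe sets, which left 16129. Counts without a filter had been seen by then. A spread that follows the mean level was replaced by a common one in eBayes, with the planned form as an alternative. Where a list gene had several probe sets, as 2 did, the probe set without a cross-hybridisation suffix and then the lowest ID was used in place of the highest mean. The median residual SD was 0.186 for tested probe sets and 0.0466 for the 6617 not tested.

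Probe sets were assigned to genes by the platform's table. Of the tested probe sets 15138 had 1 gene, 710 several and 281 none. Locus order on assembly TAIR10.1 was available for 15003 genes. A probe set reports transcripts that match its probes, which for REV and KAN1 include the transgene.

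A limma linear model (limma 3.58.1, R 4.3.3) with a mean per group was fitted to all 42 arrays, with 28 residual degrees of freedom and 3.92 prior degrees of freedom. Tests were two-sided and moderated, with Benjamini-Hochberg adjustment over the tested probe sets of each comparison and a threshold of 0.05. A line's DEX response was its change from 0 min less that of the wild type of its day. The wild-type responses at 30 and 60 min were the mean of both days and that at 120 min was of day 1. Differences between lines, between times and between days were tested as contrasts of responses. Overlaps were tested by Fisher's exact test, two-sided, per pair of directions.

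In total 22 lists with 301 entries, 211 of them tested, were examined with camera in 8 comparisons over 15007 genes (176 tests). The preset correlation between genes was 0.01, and an estimated correlation was used as the alternative. The lists were HD-ZIPIII, LITTLE ZIPPER, KANADI, abaxial and adaxial regulators, HD-ZIPII, auxin synthesis, auxin transport, Aux/IAA, GH3 and SAUR, cytokinin response, ABA signalling, gibberellin metabolism, brassinosteroid metabolism, shade response, circadian clock, touch and wound, heat shock, photosynthesis, root tissue, shoot meristem, vascular tissue and cell division. With the preset correlation 40 tests passed, and with an estimated one 11.

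Named genes were the 10 highest and 10 lowest changes of each response among probe sets of 1 gene past the threshold with the same sign against both references, and the 5 highest and 5 lowest before DEX. Added to them were REV, KAN1, all members of the first 3 lists and of HD-ZIPII, up to 4 members of each other list by adjusted p, and the 10 genes of opposite response with the largest smaller change. Those given were picked from this set. Genes of the chromosome 3 segment and BEE1 in the comparison of lines were chosen after their values were seen.

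Alternatives fixed in advance were quantile normalisation, testing all probe sets, a spread that follows the mean, robust and unmoderated spreads, array weights, a 2-fold minimum, a block for replicate number, the arrays of 1 day alone, a single reference (wild type at the same time, or the line's own 0 min), an estimated correlation, another choice of probe set, and leaving out each array in turn. Median centring, the pooled wild type of both days, each day of wild type alone, and leaving out the chromosome 3 segment or the 2-state probe sets were chosen after seeing the data. The second level filter and the second table were not run, since levels are not kept and the tables are identical. Quantile normalisation was run on the centred values. It thus equalised the arrays' distributions of differences from wild type at 0 min, not of signal levels.

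The steps were tested on simulated data, with 100 probe sets changed 2-fold and 100 changed 4-fold among 16129. Noise was normal and drawn independently for each probe set and array, with the fitted spread. The simulation thus lacks correlation between probe sets and shifts of whole arrays, and real data may do worse. At 60 min, 77 and 98 were recovered for GR-REV with 15 false calls, and 63 and 98 for KAN1-GR with 7. For GR-REV before DEX 90 and 99 were recovered with 17 false calls, and for wild type at 60 min 97 and 99 with 8. The chromosome 3 segment was found with a running median of 21 genes and a bound of 0.5. The 2-state probe sets were those at least 4-fold lower in the day 1 wild type at 0 min than in each other wild-type group.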

Results

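Transcript levels were measured on 42 Affymetrix ATH1 arrays, each with RNA of whole Arabidopsis thaliana seedlings grown for 7 days in liquid culture. The arrays fall into 14 groups of 3 by line, time and day of collection. The GR-REV line carries REVOLUTA (REV), a class III homeodomain-leucine zipper factor, fused to the steroid-binding domain of the glucocorticoid receptor. The KAN1-GR line carries KANADI1 (KAN1), a GARP-family factor, fused to the same domain. Dexamethasone (DEX, 50 µM) lets such a fusion enter the nucleus. Seedlings were frozen at 0, 30 and 60 min, and those of wild type and GR-REV also at 120 min. GR-REV was grown with wild type on day 1 and KAN1-GR with wild type on day 2. Log2 values are relative to the median of the 6 wild-type arrays at 0 min, so absolute levels are not known. The number of arrays limits the precision: the median standard error (SE) was 0.213 for a line's DEX response and 0.150 for a difference between a line and wild type at 0 min. The wild types of the 2 days differed at 0 min in 3701 of 16129 tested probe sets (22.9%), so each line was compared with the wild type of its own day. Each adjusted p is from limma.

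Before DEX each line was compared with the wild type of its day, and with 1 line per construct the transgene, its insertion and other differences of the line cannot be separated. The REV probe set (AT5G60690) was higher in GR-REV by 4.1 ± 0.12 (log2, SE, n = 3 against 3, adjusted p = 1.15e-22), at 4.33 ± 0.11 (SD) against 0.23 ± 0.16 in wild type. Among genes higher in GR-REV were TAT3 (AT2G24850), a tyrosine aminotransferase, by 3.87 ± 0.52, and BGL2 (AT3G57260), a pathogen-induced glucanase, by 3.56 ± 0.53. The receptor-like kinase gene AT1G35710 was higher by 3.45 ± 0.33. The amino acid transporter gene UMAMIT17 differed by -2.73 ± 0.41 and AT1G64590 by -3.09 ± 0.39, or -1.91 after quantile normalisation. In all, 2558 probe sets differed, 1254 higher and 1304 lower, 1231 after quantile normalisation (702 and 529) and 715 at 2-fold or more. At 0 min the GR-REV arrays did not sit together: replicates 1 and 2 had the low plastid psaA value of the day 1 wild type, and replicate 3 did not.

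A stretch of chromosome 3 was raised as a block in GR-REV. Its 217 tested genes, in locus order of assembly TAIR10.1 from CDC27a (AT3G16320) to BUB3.1 (AT3G19590), had a median difference of 1.13 (quartiles 0.86 and 1.36) at 0 min, a 2.19-fold median. Of these genes 215 were higher, and 193 passed the threshold, which is 15.4% of the 1254 probe sets higher in the line. The genes on either side, AT3G16310 and AT3G19630, differed by -0.09 and -0.09. The block and its edges were set by these 0 min differences, so none of these 0 min values tests it. The later arrays were not used to set it. Against wild type at the same time the median was 1.15 at 30 min, 1.05 at 60 min and 1.08 at 120 min. In KAN1-GR it was -0.03 at 0 min. Elsewhere in the genome the running median of 21 genes reached 0.31 at 0 min in GR-REV.

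**Figure D1:**
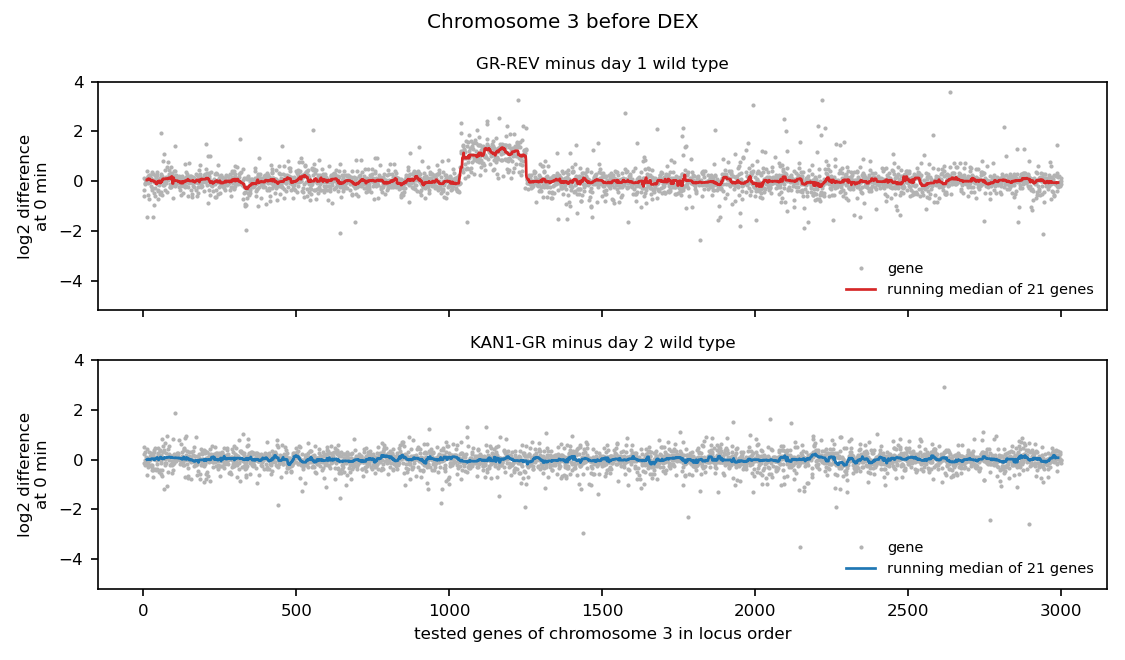
Log2 difference of each line from the wild type of its day at 0 min (y axis) for the tested genes of chromosome 3 in locus order (x axis, gene number). GR-REV is above and KAN1-GR below, grey points are genes, lines are the running median of 21 genes. In GR-REV the line steps to about the segment median of 1.13 over 217 genes, and in KAN1-GR the same genes have a median of -0.03.

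In KAN1-GR the KAN1 probe set (AT5G16560) was higher than in wild type by 9.02 ± 0.22 (log2, SE, n = 3 against 3, adjusted p = 4.16e-25), and by 5.64 after quantile normalisation. CYP716A2, a cytochrome P450 gene, was higher by 3.93 ± 0.21 (adjusted p = 4.98e-15) and GPT2, a plastid glucose 6-phosphate translocator gene, by 2.75 ± 0.47. Lower were NATA1, an acetyltransferase gene, by -5.33 ± 1.02, the caleosin gene RD20 by -4.32 ± 0.96, the defensin gene PDF1.4 by -4.29 ± 0.61 and the beta-glucosidase gene BGLU45 by -3.92 ± 0.74. Of 1730 probe sets that differed, 797 were higher and 933 lower. The count was 3947 after quantile normalisation (2019 higher and 1928 lower), 4308 with array weights and 389 at 2-fold or more. Without wild-type day 2 replicate 5 it was 1042 and without replicate 6 it was 564. Without KAN1-GR replicate 1 it was 818, and without replicate 3 it was 768.

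The GR-REV response to DEX is the change in the line from 0 min less the change in the wild type of day 1, with n = 3 arrays in each of 4 groups. At 30 min the HD-ZIPII genes, homeodomain-leucine zipper factors with roles in shade and auxin responses, gave the smallest list p of the 22. ATHB2 rose by 2.63 ± 0.28 (log2, SE, adjusted p = 3.39e-07), HAT1 by 2.22 ± 0.20, HAT22 by 2.02 ± 0.30, HAT2 by 1.80 ± 0.24 and HAT3 by 1.53 ± 0.24. HAT1 was higher by 1.15 against wild type at the same time alone. ZPR1, a LITTLE ZIPPER gene whose product binds class III factors, rose by 2.04 ± 0.31 (adjusted p = 0.000154). The ZPR1 call was lost after quantile normalisation (1.52), and its difference from wild type at the same time alone was 3.46. The largest rise was that of AT1G49200, by 3.59 ± 0.34 (adjusted p = 3.15e-08). AT1G52770 rose by 2.72 ± 0.28, the ubiquitin ligase gene RMA1 by 2.49 ± 0.30, the zinc-finger gene SHI by 2.31 ± 0.33 (1.53 against the line's own 0 min alone) and the abscisic acid (ABA) receptor gene PYL6 by 2.25 ± 0.23.

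TAA1, the aminotransferase of auxin synthesis, rose at 30 min by 1.53 ± 0.24 (adjusted p = 0.000193), a call lost after quantile normalisation (1.07). GA3ox1, which makes active gibberellin, rose by 1.61 ± 0.22 (adjusted p = 4.26e-05). AT1G79160 fell by 2.04 ± 0.32 (adjusted p = 0.000215) and AT3G60520 by 1.94 ± 0.32. Over all probe sets 223 passed, of which 139 rose and 84 fell. The count was 140 without the wild-type day 1 array at 30 min, replicate 2, and 54 after quantile normalisation (39 risen and 15 fallen). It was 638 with the wild types of both days, 1460 against wild type at the same time alone and 2749 against the line's own 0 min alone. Against wild type at the same time alone, 99 of the 139 that rose and 24 of the 84 that fell also passed. In that comparison 14 of those that rose and 26 of those that fell had the opposite sign. HSP17.6II, a small heat shock protein gene, was 1 of the latter: it was higher in GR-REV before DEX by 2.09 ± 0.25, fell by 1.72 ± 0.35 in the response, and was at 0.37 against wild type at 30 min.

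Of the HD-ZIPII genes 5 of 7 rose at 30 min, also 5 adjusted over the list alone (camera adjusted p = 3.35e-20, and adjusted p = 9.37e-08 with an estimated correlation). Of the LITTLE ZIPPER genes 1 of 2 rose, and 2 adjusted over the list alone (camera adjusted p = 2.6e-05, with an estimated correlation 0.00132). Auxin synthesis had 1 of 6 risen, TAA1, also 1 adjusted over the list alone (camera adjusted p = 0.00793, with an estimated correlation 0.036, and 0.125 when all probe sets were tested). The touch and wound list had a median of -0.88 with 1 of 21 risen and 1 fallen, and 11 fallen adjusted over the list alone (camera adjusted p = 1.51e-07). That call was lost at adjusted p = 0.147 with an estimated correlation. Photosynthesis genes had a median of 0.49 with 0 of 9 risen, and 8 adjusted over the list alone (camera adjusted p = 3.32e-08, lost at adjusted p = 0.0545 with an estimated correlation). Cytokinin response (1 of 13 risen, camera adjusted p = 0.00793), brassinosteroid metabolism (1 of 7 risen, 0.02), shade response (0 of 5, 0.00671), heat shock (1 of 6 fallen, 0.0099) and root tissue (0 of 14, 0.00185) lost their calls with an estimated correlation (adjusted p = 0.211, 0.0545, 0.0545, 0.211 and 0.121 with an estimated correlation). All of these but root tissue also lost them after quantile normalisation (adjusted p = 0.417, 0.0721, 0.0721 and 0.0530). Single arrays ended the calls of cytokinin response, without GR-REV at 30 min, replicate 2 (0.0528), of brassinosteroid metabolism, without day 1 wild type at 0 min, replicate 3 (0.0595), and GR-REV at 30 min, replicate 1 (0.138), and of heat shock, without GR-REV at 0 min, replicate 3 (0.0506). The other lists did not pass at 30 min.

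At 60 min both measured LITTLE ZIPPER genes had risen. ZPR1 rose by 3.58 ± 0.31 (log2, SE, n = 3 arrays in each of 4 groups, adjusted p = 4.53e-09), a 12-fold change, and ZPR3 by 3.44 ± 0.57 (adjusted p = 0.000222). HAT1, at 1.87 ± 0.20 (0.80 against wild type at the same time alone), HAT2, at 1.81 ± 0.24, ATHB2, at 1.69 ± 0.28, HAT3, at 1.63 ± 0.24, and HAT14, at 1.43 ± 0.30, were the risen HD-ZIPII genes. HAT22, at 0.72, was no longer past the threshold. UMAMIT33, a transporter gene, rose by 3.38 ± 0.42, AT1G70985 by 3.15 ± 0.38, iqd9, of a calmodulin-binding family, by 2.77 ± 0.26 and the ubiquitin-conjugating enzyme gene UBC17 by 2.56 ± 0.25. In auxin synthesis, YUC5, a flavin monooxygenase gene, rose by 1.76 ± 0.37 (adjusted p = 0.00279), and TAA1 by 1.37 ± 0.24, lost after quantile normalisation (0.85). WAG1, a kinase gene of auxin transport, rose by 1.27 ± 0.20 and the gibberellin methyltransferase gene GAMT2 by 2.44 ± 0.46.

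Of 7 genes of brassinosteroid metabolism 2 rose and 1 fell at 60 min. BAS1, which inactivates brassinosteroids, rose by 2.14 ± 0.40 (adjusted p = 0.000956, and 1.07 against wild type at the same time alone), and BR6OX2, which acts late in their synthesis, fell by 1.99 ± 0.28, lost after quantile normalisation (-1.3). Among the lowest were AT1G79160, which fell by 2.77 ± 0.32, AT5G01740, by 2.72 ± 0.40, and NAC6, a NAC-domain factor gene, by 2.69 ± 0.29. The NAC6 difference from wild type at the same time alone was -1.48. RD29A, a dehydration marker, fell by 1.78 ± 0.35 (-0.94 against wild type at the same time alone, and -0.57, not past the threshold, against the line's own 0 min alone). In all 704 probe sets passed, 283 risen and 421 fallen, and 284 after quantile normalisation (142 and 142). The count was 1501 with the wild types of both days, 2063 against wild type at the same time alone, 2921 against the line's own 0 min alone and 419 at 2-fold or more. Against wild type at the same time alone, 199 of the 283 risen and 218 of the 421 fallen also passed. In that comparison 12 of those risen and 58 of those fallen had the opposite sign, HSP17.6II among the latter (-2.09 ± 0.35 against 0.00134).

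By list at 60 min, 2 of 2 LITTLE ZIPPER genes rose, 2 adjusted over the list alone (camera adjusted p = 3.15e-08, with an estimated correlation 3.82e-05). Of the HD-ZIPII genes 5 of 7 rose, 6 adjusted over the list alone (camera adjusted p = 6.87e-12, with an estimated correlation 1.42e-05). In auxin synthesis 2 of 6 rose, 3 adjusted over the list alone (camera adjusted p = 0.00788, with an estimated correlation 0.0287, and 0.104 when all probe sets were tested). Touch and wound genes had a median of -1.04, with 4 of 21 fallen and 10 adjusted over the list alone (camera adjusted p = 3.15e-08). That call was lost at adjusted p = 0.160 with an estimated correlation. WRKY33, at -1.72 ± 0.48, and JAZ1, at -1.49 ± 0.44, were among the 4, and both calls were lost with wild type at the same time alone (-0.44 and -0.11) and after quantile normalisation (-1.57 and -1.09). Leaving out single arrays ended the WRKY33 call in 6 of 12 fits, those without GR-REV at 0 min, replicates 1 (-1.72) and 2 (-1.50), GR-REV at 60 min, replicate 1 (-1.32), day 1 wild type at 0 min, replicate 1 (-1.33), and day 1 wild type at 60 min, replicates 1 (-1.52) and 2 (-1.62). It ended the JAZ1 call in 8 of 12, those without GR-REV at 0 min, replicates 1 (-1.35) and 2 (-1.27), GR-REV at 60 min, replicates 1 (-1.36) and 3 (-1.38), day 1 wild type at 0 min, replicates 1 (-1.31) and 3 (-1.46), and day 1 wild type at 60 min, replicates 1 (-1.29) and 2 (-1.55). Photosynthesis, with 1 of 9 risen and 6 adjusted over the list alone (camera adjusted p = 5.25e-06), and heat shock, with 1 of 6 fallen (0.00563), lost their calls with an estimated correlation (adjusted p = 0.160 and 0.201). These responses rest on day 1 arrays, whose 0 min groups hold the low plastid values.

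The other 16 lists did not pass at 60 min in GR-REV. HD-ZIPIII had 1 of 5 fallen, PHV, at -0.74 ± 0.22 (adjusted p = 0.0483), lost against wild type at the same time alone (-0.27), after quantile normalisation (-0.54), with array weights (-0.67), when all probe sets were tested, with an unmoderated spread and in 8 of the 12 fits that left out 1 array. Those were without GR-REV at 0 min, replicates 1 (-0.66) and 2 (-0.77), GR-REV at 60 min, replicates 1 (-0.63) and 3 (-0.75), day 1 wild type at 0 min, replicates 1 (-0.68) and 3 (-0.72), and day 1 wild type at 60 min, replicates 1 (-0.71) and 3 (-0.67). PHB was at -0.25, CNA at -0.06 and ATHB8 at -0.19. KANADI (0 of 4 past the threshold, 1 risen and 3 fallen adjusted over the list alone), abaxial and adaxial regulators (0 of 8), Aux/IAA (0 of 14), cytokinin response (0 of 13), circadian clock (0 of 12), root tissue (0 of 14), shoot meristem (0 of 4) and cell division (0 of 10) had no gene past the threshold. Auxin transport had 2 of 15 risen, GH3 and SAUR 2 risen and 2 fallen of 8, ABA signalling 2 and 2 of 22, gibberellin metabolism 1 and 2 of 7, brassinosteroid metabolism 2 and 1 of 7, shade response 1 and 1 of 5, and vascular tissue 1 risen of 12. SAUR9, at 1.57 ± 0.36, was 1 of the 2 risen GH3 and SAUR genes and was lost after quantile normalisation (1.09).

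At 120 min in GR-REV, UMAMIT33 was up by 4.1 ± 0.42 (log2, SE, n = 3 arrays in each of 4 groups, adjusted p = 1.04e-07) and ZPR1 by 4.08 ± 0.31 (adjusted p = 3.66e-10), a 16.9-fold change. ZPR3, at 0.99 ± 0.57, was not past the threshold. The cytochrome P450 gene CYP78A7 rose by 2.71 ± 0.27, iqd9 by 2.43 ± 0.26 (1.56 against wild type at the same time alone) and NAC003 by 2.15 ± 0.26. The vascular genes PXY, a receptor kinase gene of the cambium, and APL, a phloem identity factor gene, changed in opposite directions. PXY rose by 1.38 ± 0.29 (adjusted p = 0.00377) and APL fell by 1.08 ± 0.19 (adjusted p = 0.000664), a call lost after quantile normalisation (-0.69). SUC2, a phloem sucrose transporter gene, fell by 0.91 ± 0.13 relative to wild type, where it had risen by 1.21 ± 0.09, and was at 0.30 against the line's own 0 min alone. KAN3 fell by 1.59 ± 0.33 (adjusted p = 0.00354).

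Over all probe sets 619 passed at 120 min, 191 risen and 428 fallen. Without wild-type day 1 replicate 1 at 0 min the count was 402, without replicate 2 of that wild type at 120 min it was 403, without GR-REV replicate 3 at 120 min it was 379, and after quantile normalisation it was 228, 106 risen and 122 fallen. It was 2489 against wild type at the same time alone, 1928 against the line's own 0 min alone and 333 at 2-fold or more. LITTLE ZIPPER had 1 of 2 risen, 1 adjusted over the list alone (camera adjusted p = 9.77e-06, with an estimated correlation 0.00132). HD-ZIPII had 3 of 7 risen, 5 adjusted over the list alone (camera adjusted p = 9.9e-05, with an estimated correlation 0.00883). These 3 were HAT1 (0.90 ± 0.20, but -0.17 against wild type at the same time alone), HAT2 (0.93 ± 0.24) and HAT3 (0.82 ± 0.24). Quantile normalisation ended all 3 calls (0.72, 0.86 and 0.81), and leaving out single arrays ended those of HAT2 and HAT3 in 7 of 12 fits each. For HAT2 these were without GR-REV at 0 min, replicate 3 (0.78), GR-REV at 120 min, replicates 1 (0.89) and 3 (0.81), day 1 wild type at 0 min, replicates 1 (0.87) and 2 (0.90), and day 1 wild type at 120 min, replicates 1 (0.84) and 3 (0.85). For HAT3 they were without GR-REV at 0 min, replicates 2 (0.75) and 3 (0.75), GR-REV at 120 min, replicate 3 (0.67), day 1 wild type at 0 min, replicates 1 (0.82) and 2 (0.78), and day 1 wild type at 120 min, replicates 2 (0.89) and 3 (0.69). KANADI had 1 risen and 1 fallen of 4. The risen gene ATS (1.27 ± 0.37, adjusted p = 0.045) was at 0.17 against wild type at the same time alone and at 0.47 against the line's own 0 min alone, neither past the threshold. It was also lost after quantile normalisation (1.32), when all probe sets were tested, with a spread that follows the mean, with robust and unmoderated spreads, with a replicate block and in 9 of the 12 fits that left out 1 array, those without GR-REV at 0 min, replicates 1 (1.19) and 2 (1.22), GR-REV at 120 min, replicates 1 (1.31), 2 (1.13) and 3 (1.36), day 1 wild type at 0 min, replicates 1 (1.3) and 2 (1.08), and day 1 wild type at 120 min, replicates 2 (1.15) and 3 (1.29). Calls of brassinosteroid metabolism (2 risen, 1 fallen of 7, adjusted p = 0.0695 with an estimated correlation), touch and wound (1 fallen of 21, 0.248) and photosynthesis (1 risen of 9, 0.0791) were lost with an estimated correlation. That of brassinosteroid metabolism was also lost after quantile normalisation (adjusted p = 0.101) and without day 1 wild type at 0 min, replicate 3 (0.0627), and day 1 wild type at 120 min, replicate 1 (0.0538). No other list passed.

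**Figure D2:**
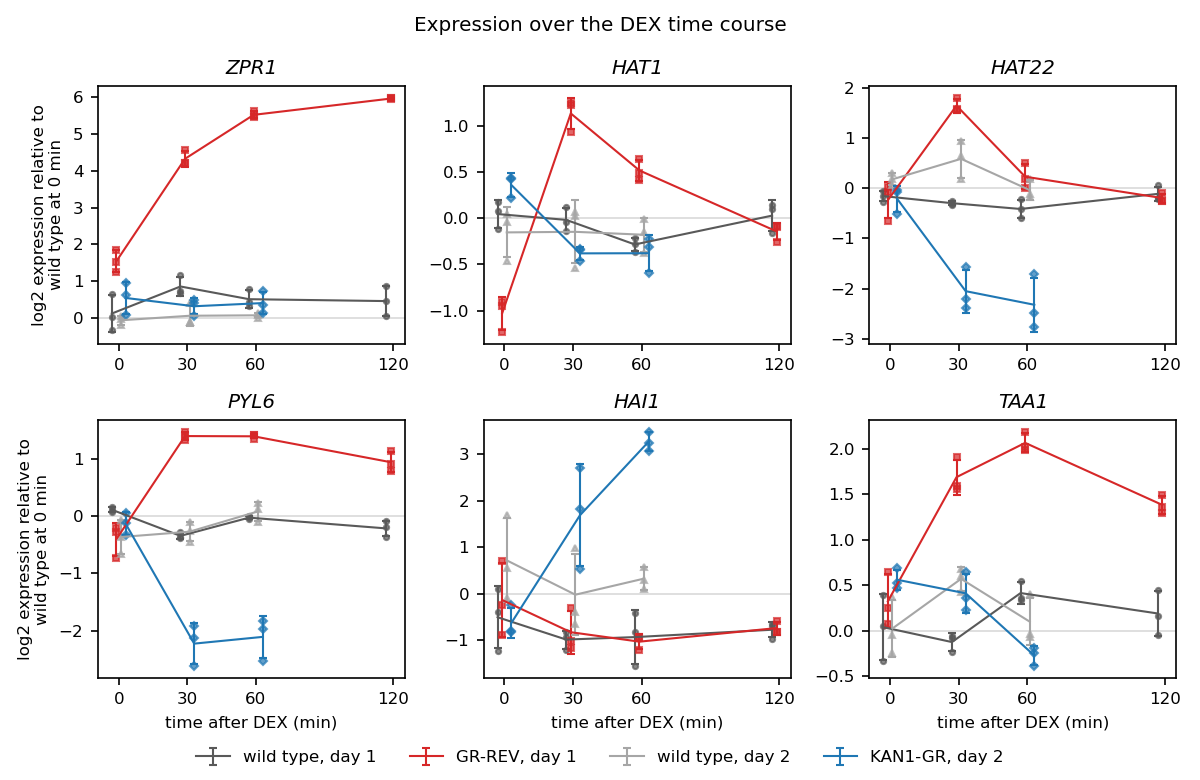
Log2 expression relative to wild type at 0 min (y axis) against time after DEX in min (x axis) for ZPR1, HAT1, HAT22, PYL6, HAI1 and TAA1 in GR-REV and wild type of day 1, and in KAN1-GR and wild type of day 2. Small points are arrays, lines join means and bars are the SD of 3 arrays. ZPR1 in GR-REV goes from 1.55 at 0 min to 5.96 at 120 min, and PYL6 reaches 1.4 in GR-REV and -2.23 in KAN1-GR at 30 min.

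KAN1-GR was compared with wild type of day 2 in the same way, with n = 3 arrays in each of 4 groups. At 30 min AT5G61590, an ERF-family factor gene, fell by 4.51 ± 0.22 (log2, SE, adjusted p = 1.4e-15), a 22.8-fold change. AT4G34770, of the SAUR family, fell by 4.18 ± 0.32 and the cation exchanger gene CAX7 fell by 3.57 ± 0.48. BR6OX2 fell by 2.62 ± 0.28 (adjusted p = 1.51e-07), the brassinosteroid-induced gene BEE1 fell by 2.60 ± 0.34 (-1.1 against the line's own 0 min alone), HAT22 fell by 2.25 ± 0.30 and PYL6 fell by 2.19 ± 0.23. KAN2, a relative of the transgene, fell by 1.68 ± 0.34 (adjusted p = 0.00265). CYP96A9, a cytochrome P450 gene, rose by 3.01 ± 0.30 (adjusted p = 3.47e-08). HAI1, a protein phosphatase gene of ABA signalling, rose by 3.05 ± 0.63 (1.71 against wild type at the same time alone), MYB45 by 2.31 ± 0.24 and NAC6 by 1.87 ± 0.29 (1.01 against wild type at the same time alone).

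At 30 min 387 probe sets passed in KAN1-GR, 112 risen and 275 fallen. The count was 256 without the wild-type day 2 array at 30 min, replicate 4, 796 after quantile normalisation (347 risen and 449 fallen) and 2207 with array weights. It was 966 with the wild types of both days, 2266 against wild type at the same time alone, 1034 against the line's own 0 min alone and 248 at 2-fold or more. Brassinosteroid metabolism, with 1 of 7 fallen and 3 adjusted over the list alone, was the 1 list past the threshold both ways (camera adjusted p = 0.00372, with an estimated correlation 0.0385, and 0.371 after quantile normalisation). The fallen gene was BR6OX2. KANADI had 2 of 4 fallen, 2 adjusted over the list alone (camera adjusted p = 0.0187, lost at adjusted p = 0.084 with an estimated correlation). The 4 include KAN1, whose probe set also reads the transgene in this line. Auxin transport (0 of 15 past the threshold, 2 fallen adjusted over the list alone, adjusted p = 0.183 with an estimated correlation), Aux/IAA (1 of 14 fallen, 0.337), GH3 and SAUR (1 of 8 fallen, 0.0963) and cytokinin response (0 of 13, 6 fallen adjusted over the list alone, 0.172) passed camera but not with an estimated correlation. The calls of KANADI, Aux/IAA, and GH3 and SAUR were also lost after quantile normalisation (adjusted p = 0.343, 0.112 and 0.419). That of Aux/IAA was lost without day 2 wild type at 0 min, replicate 6 (0.08), and KAN1-GR at 30 min, replicate 1 (0.357), and that of GH3 and SAUR without day 2 wild type at 30 min, replicate 6 (0.0603). The fallen GH3 and SAUR gene was SAUR16, at -1.90 ± 0.30. HD-ZIPII had 1 risen and 3 fallen of 7 and did not pass, nor did the other lists.

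At 60 min 3 of 22 genes of ABA signalling rose in KAN1-GR and 5 fell. HAI1 rose by 4.29 ± 0.63 (log2, SE, n = 3 arrays in each of 4 groups, adjusted p = 1.53e-05) and ABI2, another phosphatase gene, by 2.09 ± 0.15 (adjusted p = 1.7e-11). The ABA receptor genes PYL6, PYL5 and PYL4 fell by 2.42 ± 0.23, 1.68 ± 0.22 and 1.22 ± 0.12. Adjusted over the list alone, 3 rose and 7 fell, with no call (camera adjusted p = 0.192). CYP96A9 rose by 4.34 ± 0.30, CHAT, an acetyltransferase gene of leaf volatile synthesis, by 3.44 ± 0.26, the phosphate transporter gene PHT1;5 by 3.43 ± 0.41, NAC6 by 3.24 ± 0.29 and NAC080 by 3.22 ± 0.40. The linker histone gene HIS1-3 rose by 3.29 ± 0.35 (1.81 against the line's own 0 min alone), and GA20ox3, an enzyme gene of gibberellin synthesis, by 2.92 ± 0.30. The receptor-like kinase gene CRK30 fell by 5.33 ± 0.58, a 40.3-fold change, and AT3G19850 fell by 4.91 ± 0.36, AT4G34770 fell by 4.73 ± 0.32 and AT5G61590 fell by 4.34 ± 0.22.

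At 60 min in KAN1-GR the efflux carrier genes PIN4 and PIN3 fell by 2.12 ± 0.21 (adjusted p = 1.8e-08) and 0.96 ± 0.16 (adjusted p = 9.44e-05), IAA3 by 1.37 ± 0.30 and SAUR16 by 1.57 ± 0.30. TAA1 fell by 0.91 ± 0.24 (adjusted p = 0.0138), a call lost against wild type at the same time alone (-0.37), without wild-type day 2 replicate 6 at 0 min (-0.78) and without replicate 4 at 60 min (-0.76). Auxin transport had 3 of 15 fallen, 4 adjusted over the list alone (camera adjusted p = 0.00135, lost at adjusted p = 0.146 with an estimated correlation). PIF3, a phytochrome-interacting factor gene, fell by 1.63 ± 0.20. HAT22 fell by 1.90 ± 0.30 (-1.23 after quantile normalisation) and HAT2 by 1.38 ± 0.24. HAT1, at -0.71 ± 0.20 (adjusted p = 0.026), was lost after quantile normalisation (-0.65), against wild type at the same time alone (-0.20), in a fit of the day's arrays alone and in 6 of the 12 fits that left out 1 array. Those were without KAN1-GR at 0 min, replicates 2 (-0.67) and 3 (-0.68), KAN1-GR at 60 min, replicate 2 (-0.60), day 2 wild type at 0 min, replicate 6 (-0.56), and day 2 wild type at 60 min, replicates 5 (-0.70) and 6 (-0.63).

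Also at 60 min, KAN3 fell by 2.01 ± 0.33 (adjusted p = 7.29e-05), AS2, which promotes upper leaf fate, by 1.26 ± 0.27, and the YABBY genes FIL and YAB5 by 1.08 ± 0.19 and 0.99 ± 0.23. FIL was at -0.50 against wild type at the same time alone and at -0.71 against the line's own 0 min alone. YAB3, at -0.83 ± 0.23, was lost without wild-type replicate 6 at 60 min (-0.74), KAN1-GR replicate 1 at 0 min (-0.71) or replicate 2 at 60 min (-0.76), and against wild type at the same time alone (-0.07). KAN2, at -1.1 ± 0.34 (adjusted p = 0.0453), was lost after quantile normalisation (-0.97), when all probe sets were tested, in a fit of the day's arrays alone, with an unmoderated spread, with a replicate block and in 8 of the 12 fits that left out 1 array. Those were without KAN1-GR at 0 min, replicates 2 (-1.04) and 3 (-1.04), KAN1-GR at 60 min, replicates 2 (-0.94) and 3 (-1.13), day 2 wild type at 0 min, replicates 5 (-1.12) and 6 (-0.97), and day 2 wild type at 60 min, replicates 4 (-1.04) and 6 (-0.87). Abaxial and adaxial regulators had 4 of 8 fallen, 5 fallen and 1 risen adjusted over the list alone (camera adjusted p = 0.0169, lost at adjusted p = 0.134 with an estimated correlation). KANADI, with KAN1 and thus the transgene among its 4 genes, had 2 of 4 fallen, 2 adjusted over the list alone (camera adjusted p = 0.0289, lost at adjusted p = 0.134 with an estimated correlation, and 0.230 after quantile normalisation). The KANADI call was also lost without day 2 wild type at 0 min, replicate 6 (0.0599), day 2 wild type at 60 min, replicate 4 (0.053), and KAN1-GR at 60 min, replicates 1 (0.0666) and 2 (0.0755). REV itself was at -0.64 ± 0.17 (adjusted p = 0.0145) and was lost with a spread that follows the mean, with a robust spread, in a fit of the day's arrays alone, with the wild types of both days (-0.38), after quantile normalisation and without KAN1-GR at 60 min, replicate 2 (-0.50), day 2 wild type at 0 min, replicate 6 (-0.57), and day 2 wild type at 60 min, replicate 6 (-0.56). No other list passed at 60 min in KAN1-GR. In all 1103 probe sets passed, 464 risen and 639 fallen, and 1692 after quantile normalisation (822 and 870). The count was 1738 with the wild types of both days, 2898 against wild type at the same time alone, 1984 against the line's own 0 min alone and 615 at 2-fold or more.

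The lines were compared to find genes that REV and KAN1 move in opposite directions. At 60 min 96 probe sets passed in both lines with opposite signs and 82 with the same sign. Were the calls of the lines independent, 23.3 and 24.8 would be expected. Both numbers exceeded this, so an excess is not particular to opposite signs. PYL6 (1.93 in GR-REV and -2.42 in KAN1-GR), HAT2 (1.81 and -1.38) and AT1G70985 (3.15 and -2.44, the latter -1.58 against the line's own 0 min alone) rose in GR-REV and fell in KAN1-GR. NAC6 (-2.69 and 3.24), ABCG18, a transporter gene (-2.07 and 2.11), and BT4, a scaffold protein gene (-1.55 and 1.5), fell in GR-REV and rose in KAN1-GR. Against wild type at the same time alone NAC6 was at -1.48 and BT4 at -0.81 in GR-REV, and after quantile normalisation ABCG18 was at 1.33 in KAN1-GR. The difference between the lines was -5.93 ± 0.41 for NAC6 (log2, SE, n = 3 arrays in each of 8 groups). After quantile normalisation 39 probe sets moved in opposite directions, at 2-fold or more 45 did, with the wild types of both days 221, against wild type at the same time alone 329, and against each line's own 0 min alone 473. With the same sign, ATHB2 rose in both lines (1.69 and 1.66, the latter 0.82 and not past the threshold after quantile normalisation). BR6OX2 (-1.99 and -1.31) and BEE1 (-1.80 and -2.44), the latter chosen after its values were seen, fell in both. BR6OX2 was at -1.3 in GR-REV after quantile normalisation, not past the threshold, and at -0.77 in KAN1-GR against wild type at the same time alone.

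Of the 96, 42 rose in GR-REV and fell in KAN1-GR (11.2 expected, two-sided Fisher's exact p = 1.23e-13) and 54 did the reverse (12.1 expected, p = 1.41e-20). Of the 82, 23 rose in both (8.14 expected, Fisher's exact p = 7.90e-06) and 59 fell in both (16.7 expected, p = 1.68e-17). Fisher's test takes probe sets as independent, which they are not, so these p-values do not measure the spread between seedlings. At 30 min 30 were opposite (2.95 expected) and 8 had the same sign (2.40 expected). Across the 16129 probe sets, which are not independent replicates, Pearson's r of the responses was -0.0637 at 30 min and -0.0878 at 60 min, and Spearman's rho was -0.0346 and -0.0486. The responses share no array. By the test of the difference itself, 363 probe sets differed between the lines at 30 min (252 higher in GR-REV) and 1026 at 60 min (497 higher). With array weights the count at 30 min was 1065. TAA1 and HAT1, higher in GR-REV by 2.28 ± 0.34 and 2.58 ± 0.29 at 60 min, were among them.

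**Figure D3:**
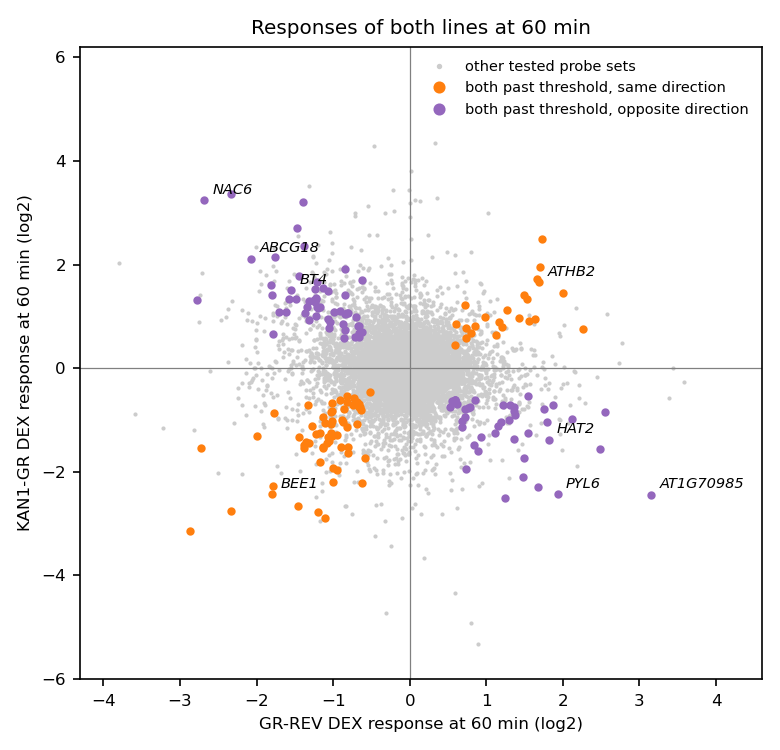
Log2 DEX response at 60 min of each tested probe set in GR-REV (x axis) and KAN1-GR (y axis). Purple points are the 96 probe sets past the threshold in both lines with opposite signs, orange points the 82 with the same sign, and grey points all others. NAC6 lies at -2.69 and 3.24, and PYL6 at 1.93 and -2.42.

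Wild type, which has no fusion, was compared with its own 0 min. All later seedlings had DEX, so DEX, time and handling cannot be separated in these responses. In day 1 wild type the control probe set bioB-3 was at 0.85 to 1.04 at 30 min and 0.07 to 0.23 at 0 min. Array processing may thus differ between these times as well. At 30 min type-A response regulator genes of cytokinin signalling rose: ARR7 by 1.73 ± 0.15 (log2, SE, n = 6 against 6, adjusted p = 7.47e-09), ARR15 by 1.53 ± 0.19 and ARR6 by 1.07 ± 0.14. ARR15 was at 0.52 on day 1 alone, not past the threshold, and at 2.55 on day 2 alone, and ARR7 was at 1.07 on day 1 alone. The F-box gene AT2G44130 rose by 1.57 ± 0.17 at 30 min, 2.65 ± 0.17 at 60 min and 3.64 ± 0.24 at 120 min (n = 3 against 3). At 30 min EXPA7, a root hair expansin gene, fell by 1.24 ± 0.21 (adjusted p = 0.000433) and RSL4, a root hair factor gene, by 1.20 ± 0.21. CASP1 and CASP2, of the Casparian strip, were at -0.55 ± 0.12 and -0.61 ± 0.14, and neither passed on day 2 alone (-0.21 and -0.48). The copper transporter gene COPT2 fell by 1.93 ± 0.33 at 30 min, -3.53 on day 1 and -0.33, not past the threshold, on day 2. At 120 min, on day 1 only, COPT2 fell by 3.52 ± 0.47, DFR, of anthocyanin synthesis, by 1.89 ± 0.37, and SUC2 rose by 1.21 ± 0.09.

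Of the 10 highest wild-type rises, 9 at 30 min, 9 at 60 min and 8 at 120 min were of a set of 35 probe sets. These were at least 4-fold lower in the day 1 wild type at 0 min than in each other wild-type group. A rise on day 1 follows from that choice, so their place among the highest rises is no separate result. SPL1 rose by 3.06 ± 0.53 at 30 min, SIZ1, a SUMO ligase gene, by 2.21 ± 0.51 and ZIGA4 by 2.25 ± 0.40 (n = 6 against 6). On day 1 alone they were at 6.03, 4.46 and 4.21, and on day 2 alone at 0.09, -0.04 and 0.30, none of them past the threshold. At 120 min, on day 1 only, SPL1 was at 5.89 ± 0.75, SIZ1 at 4.44 ± 0.72 and ZIGA4 at 4.11 ± 0.57. Plastid-encoded transcripts made up 9 of the 35, of 65 tested (two-sided Fisher's exact p = 1.02e-14). The set was chosen on these data and its probe sets are not independent, so this p does not measure the spread between seedlings. The low values were also in GR-REV replicates 1 and 2 at 0 min.

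By list, cytokinin response had 5 of 13 risen at 30 min in wild type, 9 risen and 1 fallen adjusted over the list alone (camera adjusted p = 2.28e-10, with an estimated correlation 0.0108). Root tissue had 5 of 14 fallen, 5 adjusted over the list alone (camera adjusted p = 4.56e-06, with an estimated correlation 0.0459). Touch and wound had 5 of 21 risen, 10 adjusted over the list alone (camera adjusted p = 5.19e-05, lost at adjusted p = 0.405 with an estimated correlation). WRKY33, at 1.1 ± 0.24, was 1 of the 5 and did not pass on day 2 alone (1.01). ABA signalling (2 of 22 fallen), shade response (2 of 5 fallen), Aux/IAA (2 of 14 risen), vascular tissue (1 of 12 risen), HD-ZIPIII (0 of 5) and photosynthesis (0 of 9) passed camera but not with an estimated correlation (lowest adjusted p = 0.118 with an estimated correlation). Single arrays ended the call of ABA signalling, without day 1 wild type at 0 min, replicates 2 (0.0536) and 3 (0.0629), day 1 wild type at 30 min, replicate 1 (0.0521), and day 2 wild type at 30 min, replicate 5 (0.0658), and that of Aux/IAA, without day 1 wild type at 0 min, replicates 1 (0.0725) and 2 (0.0779), day 2 wild type at 0 min, replicate 6 (0.157), day 1 wild type at 30 min, replicate 3 (0.109), and day 2 wild type at 30 min, replicates 4 (0.0885) and 5 (0.0801). They ended that of HD-ZIPIII, without day 1 wild type at 0 min, replicates 2 (0.0502) and 3 (0.134), day 2 wild type at 0 min, replicates 4 (0.0612) and 5 (0.0682), day 1 wild type at 30 min, replicates 1 (0.0806) and 3 (0.0559), day 2 wild type at 30 min, replicates 4 (0.115) and 5 (0.0904), GR-REV at 0 min, replicate 3 (0.0512), and KAN1-GR at 60 min, replicate 1 (0.0508), and that of vascular tissue, without day 1 wild type at 0 min, replicates 2 (0.0878) and 3 (0.06), day 2 wild type at 0 min, replicate 6 (0.0854), day 1 wild type at 30 min, replicates 1 (0.0521), 2 (0.0593) and 3 (0.0559), day 2 wild type at 30 min, replicates 4 (0.115) and 5 (0.0684), GR-REV at 0 min, replicate 3 (0.0512), and KAN1-GR at 60 min, replicate 1 (0.0508). They ended that of photosynthesis, without day 1 wild type at 0 min, replicate 2 (0.0502). Vascular tissue and photosynthesis were lost after quantile normalisation as well (0.0697 and 0.111). At 60 min no list passed. At 120 min photosynthesis (1 of 9 fallen, adjusted p = 0.957 with an estimated correlation) was the 1 call, at camera adjusted p = 0.049. It was lost after quantile normalisation (0.108), median centring (0.0547) and without each of these arrays in turn: day 1 wild type at 0 min, replicates 1 (0.0994) and 2 (0.0931), day 2 wild type at 0 min, replicate 5 (0.0506), day 1 wild type at 30 min, replicates 1 (0.0513) and 3 (0.0512), day 2 wild type at 30 min, replicate 5 (0.0536), day 2 wild type at 60 min, replicates 4 (0.0518), 5 (0.0526) and 6 (0.0515), day 1 wild type at 120 min, replicate 2 (0.504), GR-REV at 0 min, replicates 1 (0.0537), 2 (0.0543) and 3 (0.0573), GR-REV at 30 min, replicate 1 (0.0529), GR-REV at 120 min, replicates 1 (0.0516), 2 (0.0516) and 3 (0.0506), KAN1-GR at 0 min, replicate 2 (0.0516), and KAN1-GR at 30 min, replicate 2 (0.0514). The circadian clock had 2 risen and 2 fallen of 12 at 120 min. PRR3, at 1.47 ± 0.33, was lost without day 1 replicate 2 at 0 min (1.04) or replicate 2 at 120 min (1.24), and CCA1, at -0.95 ± 0.23, was lost in 4 of the 6 fits that left out 1 array, those without day 1 wild type at 0 min, replicates 1 (-0.79) and 2 (-0.90), and day 1 wild type at 120 min, replicates 2 (-0.84) and 3 (-0.78).

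In wild type 624 probe sets passed at 30 min (326 risen, 298 fallen), 376 at 60 min (263 and 113) and 828 at 120 min (616 and 212). On day 1 alone 1601 passed at 30 min, 461 of the 624 among them, and 667 at 60 min, 228 of the 376 among them. On day 2 alone 97 passed at 30 min, 66 of the 624 among them, and 77 at 60 min, 35 of the 376 among them. After quantile normalisation the counts were 1137 (552 risen, 585 fallen), 979 (519 and 460) and 1654 (818 and 836), and with median centring 436 rose and 381 fell at 120 min. The day 1 array at 120 min, replicate 2, had a median of 0.189, the highest of all arrays. Median centring removes such a shift, so the excess of rises at 120 min rests in part on it. At 2-fold or more the counts were 107, 61 and 182, and with array weights 3208 at 30 min and 970 at 60 min. Left-out arrays moved them. At 30 min the count was 377 without day 2 replicate 5 at 0 min, 409 without day 1 replicate 3 at 30 min and 384 without day 2 replicate 4 at 30 min. At 60 min it was 186 without day 1 replicate 2 at 0 min, 223 and 130 without day 2 replicates 5 and 6 at 0 min, 187 and 245 without day 1 replicates 2 and 3 at 60 min, and 219, 228 and 224 without day 2 replicates 4, 5 and 6 at 60 min. At 120 min it was 543 and 356 without day 1 replicates 1 and 2 at 0 min, and 324 and 531 without replicates 2 and 3 at 120 min. The response at 60 min differed between the days in 225 probe sets, 144 higher on day 1 and 81 lower. This count was 1863 after quantile normalisation (904 and 959), 1065 with array weights and 111 at 2-fold or more. It was 116 without day 1 replicate 2 at 0 min, 350, 137 and 81 without day 2 replicates 4, 5 and 6 at 0 min, 79 without day 1 replicate 2 at 60 min, and 137 and 93 without day 2 replicates 4 and 6 at 60 min.

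Changes of the responses over time were tested within each line. From 30 to 120 min in GR-REV the response of CYP78A7 grew by 2.41 ± 0.27 (log2, SE, n = 3 arrays in each of 4 groups), that of UMAMIT33 by 2.30 ± 0.42 and that of ZPR1 by 2.03 ± 0.31 (adjusted p = 0.00024). The responses of AT1G49200, HAT22, ATHB2 and HAT1 changed by -2.20 ± 0.34, -2.02 ± 0.30 (adjusted p = 0.000179), -1.96 ± 0.28 and -1.32 ± 0.20. In KAN1-GR, CHAT grew by 3.67 ± 0.26 (adjusted p = 3.77e-11) from 30 to 60 min, GA20ox3 by 2.40 ± 0.30, ABI2 by 1.27 ± 0.15, and PIN4 changed by -1.41 ± 0.21. In GR-REV 248 probe sets changed, 61 up and 187 down, 56 after quantile normalisation (24 and 32), 389 with array weights and 158 at 2-fold or more. It was 164 without wild-type replicate 1 at 30 min, 154 without wild-type replicate 2 at 120 min, 151 without GR-REV replicate 1 at 30 min and 162 without GR-REV replicate 3 at 120 min. In KAN1-GR 56 changed, 33 up and 23 down, 240 with array weights and 10 in a fit of the day's arrays alone. It was 37 without wild-type replicate 5 at 30 min and 36 without wild-type replicate 4 at 60 min.

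The deposited p-values of the authors' test for an interaction of genotype and time were below 0.05 for 495 probe sets in GR-REV, 676 in KAN1-GR and 104 in both. The values were rebuilt to within 6.19e-05 from 27 arrays, with the wild types of both days at 0, 30 and 60 min and adjustment over the probe sets. With the wild type of the same day alone (18 arrays), 288 and 537 were below 0.05. Of the 762 probe sets called here at 30 or 60 min in GR-REV, 390 were below 0.05 by the authors' values, and of 1159 in KAN1-GR, 571 were.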

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

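The tests of the chromosome 3 segment and of the 2-state probe sets, and the splits of samples after removing the change common to the groups, were chosen after the results were seen.

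The responses of the lines differed in 363 probe sets at 30 min and 1026 at 60 min by the test of the difference. Of 100 splits of the samples, 3 gave as many at 30 min (highest other 1670) and 2 at 60 min (highest other 1180), and after removing the common change 1 did at each time, the real one (highest others 18 and 10). Chance can be excluded for both counts. At 60 min the 10 genes with the largest opposite responses were chosen for their opposite signs, so a test of their difference adds nothing. The log2 differences were -5.93 for NAC6, 5.60 for AT1G70985, -5.70 for AT4G29570, -4.18 for ABCG18, 4.36 for PYL6, -3.91 for AT1G20823, 3.96 for AT2G40435, -3.42 for AT3G60520, 4.05 for AT2G31110 and -3.06 for BT4. Some of the calls of a single line behind them were lost. AT2G40435 in GR-REV was lost after quantile normalisation (1.66), against the line's own 0 min alone (0.85), with array weights (1.52), when all probe sets were tested, in a fit of the day's arrays alone, with an unmoderated spread, and without GR-REV at 0 min, replicates 1 (1.63) and 3 (1.29), GR-REV at 60 min, replicates 1 (1.66) and 2 (1.55), day 1 wild type at 0 min, replicates 1 (1.77) and 2 (1.44), and day 1 wild type at 60 min, replicates 2 (1.44) and 3 (1.71). In KAN1-GR it was lost after quantile normalisation (-0.84). Against wild type at the same time alone it was larger in each line, 3.1 in GR-REV and -3.66 in KAN1-GR. AT4G29570 in GR-REV was lost against wild type at the same time alone (-0.85), and without GR-REV at 60 min, replicate 3 (-2.18), day 1 wild type at 0 min, replicate 1 (-2.10), and day 1 wild type at 60 min, replicate 1 (-1.89). After quantile normalisation AT4G29570 and AT1G20823 were lost in GR-REV (-1.70 and -1.16) and in KAN1-GR (2.09 and 1.28). AT2G31110 in KAN1-GR was lost after quantile normalisation (-1.37), in a fit of the day's arrays alone and without day 2 wild type at 60 min, replicate 5 (-1.37), and was at -0.82 against wild type at the same time alone. For the 96 probe sets of opposite sign, 2 of 100 splits gave as many (highest other 119), and 1 after removing the common change (highest other 0), so chance can be excluded.

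Between 30 and 120 min the GR-REV response changed in 248 probe sets, and between 30 and 60 min the KAN1-GR response changed in 56. As many were given by 11 and 17 of 100 plain splits (highest others 1199 and 495), so chance cannot be excluded for either by these splits. After removing the common change 1 and 4 splits did (highest others 2 and 438), a share under 0.05. The common change was computed with the real labels, which favours the real split, so these splits do not exclude chance either. The wild-type response at 60 min differed between days in 225 probe sets, as many as in 2 of 100 splits (highest other 376) and 1 after removing the common change (highest other 4), so chance can be excluded. Among the probe sets without an ANOVA p-value, left out of the tests, 18 passed for GR-REV and 34 for KAN1-GR at 60 min when all were tested.

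For the lines' responses, plain splits gave as many probe sets as the real 223, 704 and 619 of GR-REV at 30, 60 and 120 min in 16, 10 and 8 of 100 (highest others 4299, 2389 and 2489), and as many as the real 387 of KAN1-GR at 30 min in 5 (highest other 564). Chance cannot be excluded for these by plain splits. Some splits called several times the real count. Labels were exchanged only between 2 times of the same line and day. A split that swaps the times of 1 group in full turns the difference of 2 changes into their sum. Changes over time common to line and wild type then count, so plain splits are not a clean reference for these responses. After removing the common change the numbers were 3, 1, 2 and 1 (highest others 314, 199, 732 and 186), shares under 0.05. The common change was computed with the real labels, which favours the real split. This version was also chosen after the plain one was seen, so chance is not excluded by it. For the 1103 of KAN1-GR at 60 min the number was 1 in each version (highest others 1007 and 155). For wild type 3 of 100 splits gave as many as the real 624 at 30 min (highest other 1637). As many as the real 376 at 60 min came from 1 (highest other 230), so chance can be excluded for both. This does not separate DEX from time, handling or array processing. The 3 comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. The real counts there were 2558 for GR-REV before DEX, 1730 for KAN1-GR before DEX and 828 for wild type at 120 min, each reached by 1 split, with highest others 36, 2 and 183.

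A block of 217 genes on chromosome 3 was higher in GR-REV before DEX, with a median of 1.13. Processing of the 0 min arrays alone is argued against by the later arrays, where the smallest median against wild type at the same time was 1.05. Sequence differences in the line under the probes would lower a signal, so they are argued against by the direction of the block, which was searched for in both directions. That 99.5% of its genes were higher at 60 min adds little, since the edges of the block were set by raised genes at 0 min. Whether the line has an extra copy of the segment cannot be told: the largest median at later times was 1.15, inside bounds of 0.5 and 1.6, but these were set after the 0 min median was seen, and any stable property of the line would give the same. No DNA was measured here, and a biological explanation from the study's groups cannot be separated from this, since every GR-REV array comes from the 1 line.

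The 2-state probe sets, 35 in number, were low in the day 1 wild type at 0 min. Of the line arrays at 0 min 2 of 6 were low, but this count cannot decide on a response to time or DEX. The KAN1-GR arrays among them are of day 2, whose wild type at 0 min was not low by the choice of the set. On day 1 GR-REV replicates 1 and 2 were low at 0 min, and replicate 3, a single array, was not. The arrays of 1 group split: GR-REV replicate 3 at 0 min lay above replicates 1 and 2 by a median of 4.06 over these probe sets. A step of array processing or RNA preparation that some day 1 samples shared may account for this, and which step cannot be read from the values. Of the set, 9 are plastid-encoded. No biological explanation was tested beyond time and DEX, for which the test was not decisive.

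At 60 min 82 probe sets moved the same way in both lines, BR6OX2 and ATHB2 among them. Of the 82, 66 also passed in both lines against the line's own 0 min, as did 79 of the 96 of opposite sign. The same line arrays were used to select the 82, which favours such passes. The 66 are therefore only weak ground against a change in the wild types alone. The GR domain, or an insertion effect common to both lines, could account for the 82 probe sets. Neither can be told apart from a shared target of REV and KAN1, since the series has 0 lines with the GR part alone. A shared target stays open and untested.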

How the results depend on the processing

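Median centring, the pooled wild type, the single days of wild type, and leaving out the chromosome 3 segment or the 2-state probe sets were chosen after the results were seen.

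Counts stayed within 1.5 times their value with no filter, median centring, a spread that follows the mean, robust and unmoderated spreads and a replicate block (693 for GR-REV and 1093 for KAN1-GR at 60 min with the block, although replicate numbers do not pair the samples), and without the segment (2311 for GR-REV before DEX) or the 2-state probe sets (577, 329 and 752 for wild type). Others moved, and the cause was not tested except where noted. Quantile normalisation was run on centred values, so it gave all arrays the same spread of differences from wild type at 0 min. A call lost or gained with it can follow from this step alone. In the order GR-REV 30, 60 and 120 min, KAN1-GR 30 and 60 min, quantile normalisation gave 54, 284, 228, 796 and 1692. It gave 1231 and 3947 for the lines before DEX, 1137, 979 and 1654 for wild type, 56 for GR-REV over time, 1863 between days and 39 of opposite sign. The rises and falls were then 106 and 122 for GR-REV at 120 min, 347 and 449 for KAN1-GR at 30 min, 519 and 460 for wild type at 60 min, 818 and 836 at 120 min, 24 and 32 over time and 904 and 959 between days, and with median centring 436 and 381 for wild type at 120 min. Array weights gave 2207 for KAN1-GR at 30 min, 4308 before DEX, 3208 and 970 for wild type at 30 and 60 min, 1065 between lines at 30 min, 389 and 240 over time in GR-REV and KAN1-GR, and 1065 between days. Of all 42 arrays the lowest weights were 0.296 and 0.299. The highest was 6.77, for day 2 wild type at 30 min, replicate 4, in the same group as the 0.299. In KAN1-GR at 30 min, replicate 2 had 3.55 beside 0.392 and 0.445. With array weights such groups rest mostly on 1 array, which bears on the raised counts. A 2-fold minimum, which can only lower a count, gave 419 and 333 for GR-REV at 60 and 120 min, 248 and 615 for KAN1-GR, 715 and 389 before DEX, 107, 61 and 182 for wild type, 158 for GR-REV over time, 111 between days and 45 of opposite sign.

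Against wild type at the same time alone, which keeps differences present before DEX, the 5 responses had 1460, 2063, 2489, 2266 and 2898, and 329 of opposite sign. Against the line's own 0 min alone they had 2749, 2921, 1928, 1034 and 1984, and 473. With the wild types of both days, GR-REV had 638 and 1501, KAN1-GR 966 and 1738, with 221 of opposite sign. In a fit of its day alone KAN1-GR over time had 10. Wild type on day 2 had 97 at 30 min and 77 at 60 min, and on day 1 had 1601 and 667. With an estimated correlation 11 lists passed of the 40.

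Values turned sign against wild type at the same time alone for CYP707A4 (2.17, 1.56 and 1.54 at 30, 60 and 120 min), HSP17.6II (0.37, 0.00134 and 0.26), CASP1 (-0.68 and -0.90 at 30 and 60 min), CASP2 (-0.88 and -1.09), HAT1 (-0.17 at 120 min) and REV (3.86 at 120 min) in GR-REV, and for KAN1 (8.99 and 8.46) and RSL4 (-1.43 at 30 min) in KAN1-GR. Against the line's own 0 min alone SUC2 was at 0.30 in GR-REV at 120 min and ATS at -0.91 in KAN1-GR at 30 min. In wild type SIZ1 was at -0.038 and -0.034 on day 2, and ATHB2 at -0.17 on day 1 at 30 min.

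Leaving out 1 array at a time gave 140 to 242, 495 to 892 and 379 to 776 for GR-REV at 30, 60 and 120 min, 256 to 520 and 806 to 1097 for KAN1-GR, 1857 to 2458 and 564 to 1700 before DEX, 377 to 757, 130 to 400 and 324 to 1125 for wild type, 287 to 417 and 850 to 1240 between lines, 151 to 333 and 36 to 73 over time, 79 to 350 between days and 35 to 44 for lists. A group is then left with 2 arrays, and the spread comes from all groups. Same-day fits give no value for contrasts across days. Signal over background cannot be read from centred values, so what weak probe sets limit is not known.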

Other observations

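The values of psaA and of the 2-state probe sets were picked after they were seen. The plastid transcript psaA was at or below -4.21 in the 3 day 1 wild-type arrays and in GR-REV replicates 1 and 2 at 0 min, and at 1.35 or above in the other 37 arrays. KAN1-GR replicate 1 at 60 min had a median of -0.89 over the 2-state probe sets, where the other KAN1-GR arrays were above 1. The actin 5' control probe set was at -0.884 in this array, the lowest of all arrays, and psaA was at 1.35. The array is 1 of the 3 behind each KAN1-GR result at 60 min, and its RNA quality was not tested. CYP707A4, an ABA 8'-hydroxylase gene that lies within the raised block on chromosome 3, was higher in GR-REV than in wild type before DEX by 3.27 ± 0.20 (SE, n = 3 against 3, limma adjusted p = 3.18e-13). Its response at 60 min was -1.71 ± 0.28, and against wild type at the same time alone it was 1.56.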
